A study of Homo sapiens with 3 samples.

How the data were processed

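RNA sequencing was carried out on HUDEP-2 cells, an immortalised erythroid progenitor line made from umbilical cord blood. Per the labels, lentiviruses carried short hairpin RNAs (shRNAs) against MAZ or a scrambled sequence, transduced cells were sorted on EGFP and expanded, and libraries were made from total RNA and sequenced on a BGISEQ instrument. The labels put 1 library in the control shRNA group and 2 libraries in the MAZ knockdown group. They do not say whether the knockdown libraries carried the same hairpin or came from separate cultures. The spread behind the p-values of single genes comes from these 2 knockdown libraries alone and may be technical.

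The deposited files hold whole-number counts per gene symbol, 1 file per library, with no normalization and the same 28307 symbols. The build was hg38 per the submitters' processing notes. The aligner, the counting tool, its annotation, its strand setting and its treatment of reads with several matches are not given in the sources used here. Genes with near-identical copies, such as HBG1 and HBG2 or HBA1 and HBA2, could therefore share or lose reads. Sums over the copies were used for the γ-globin share and for γ-globin and α-globin levels. Ratios corrected for transcript length and counts of list members take each copy singly. Antisense and overlapping genes could not be told apart for the same reason. No mitochondrial transcript of the list fixed for them was among the symbols, so those were not analysed here.

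Total counts were 16218459 for the control, 15289779 for MAZ knockdown replicate 1 and 16604923 for MAZ knockdown replicate 2. Intervals on shares of counts are exact (Clopper-Pearson) binomial 95% intervals, and those on single counts and their ratios are exact Poisson 95% intervals. Both cover counting error only, because reads without molecular identifiers are not independent molecules.

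Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on group, which left 12712, library sizes were scaled by TMM, and the knockdown group was compared with the control by the quasi-likelihood test (two-sided, design with group as its only term, Benjamini-Hochberg adjusted p under 0.05). With 3 libraries and 2 groups there is 1 residual degree of freedom, which comes from the knockdown pair. The lone control library is assumed to vary like that pair, and the spread is moderated across genes. An exact permutation test of 1 library against 2 cannot give a p below 0.333, so none was used. Standard errors are the log2 fold change divided by the square root of the test statistic. Ratios of each knockdown library to the control are of TMM-scaled counts relative to library size (CPM) on the log2 scale with a prior count of 2, which understates changes of low genes.

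The samples, tests, named-gene rule, 32 gene lists and alternative analyses were fixed before the data were examined. Named genes were MAZ; every globin gene past the filter; BCL11A, ZBTB7A, MYB, KLF1 and GATA1; up to 3 members of every other list past the test over all genes with the same sign in both knockdown libraries; and, over all genes, the 12 higher and 12 lower genes with the largest fold change among those past the test with a mean of 5 CPM or more and the same sign in both libraries. Symbols of unnamed loci, XIST and Y-linked genes were left out. Places left empty in the last part were filled by the genes whose smaller log2 ratio was largest in size, which did not pass the test. That rule allowed no others; the further genes named are a departure from it, were chosen after their values were seen, and are marked as such.

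Lists with 5 or more tested members were tested with camera from limma 3.58.1 (preset correlation of 0.01, two-sided, Benjamini-Hochberg adjusted over the lists). For 30 lists this could be done. The median of each list was also set against 10000 random lists of the same size matched on mean expression in 20 bins. The value that a shared control gives with no effect was taken from 100 simulated sets of 3 unchanged libraries with the fitted dispersions.

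Transcript lengths and GC content came from GENCODE 29 (26287 of the 28307 symbols matched), using 1 transcript per gene, and gene positions from RefSeq on GRCh38.p14 (27191 symbols matched), the same assembly as hg38. After seeing the data, an alternative was added in which a loess surface (span 0.3) of each knockdown ratio on log2 length and GC content was taken out. The alternatives fixed beforehand were RLE and upper-quartile scaling, removal of globin genes before scaling, no filter on low counts, a filter at a mean of 5 CPM, DESeq2 1.42.0, limma-voom, robust and legacy estimation, a fixed coefficient of variation of 0.2, a prior count of 0.5, camera with an estimated correlation, fry, and leaving out either knockdown library, which leaves 1 library against 1 and so gives values with no test.

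The methods were tested on simulated data drawn from the real means, library sizes and dispersions with 200 genes changed, for the comparison of MAZ knockdown with control. Of 67 genes changed by 1 on the log2 scale 2 were recovered, of 67 changed by 3 there were 61, and of 66 changed by 5 there were 65, with 19 false calls among 12471 genes tested. In a simulation with 1 list moved by 0.5 on the log2 scale, camera with the preset correlation called that list and 0 of the other lists, while an estimated correlation gave it an adjusted p of 0.940. The list simulation used a coefficient of variation of 0.2 for every gene and drew genes independently. It therefore cannot show false calls that arise from correlation between the genes of a list. Figures were drawn with matplotlib 3.10.9.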

Results

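The role of MAZ, a zinc finger transcription factor, in the regulation of γ-globin was addressed by RNA sequencing of HUDEP-2 cells with a control shRNA (1 library) or with shRNAs against MAZ (2 libraries). The libraries held 16218459 counts in the control, 15289779 in knockdown replicate 1 and 16604923 in knockdown replicate 2, and 12712 genes were tested. There was no second control library, so no difference from the control has a replicate check on the control side.

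MAZ mRNA (chromosome 16, 29806124 to 29811164, hg38) was lower in both knockdown libraries. Its normalised level was 481 CPM in the control (95% counting interval 471 to 492), 129 CPM in replicate 1 (123 to 136) and 168 CPM in replicate 2 (162 to 174), which is 26.9% and 34.9% of the control. The knockdown mean was 149 ± 27.4 CPM (SD, n = 2). The fitted log2 fold change of MAZ was -1.69 (SE 0.57) and did not pass the test over all genes (edgeR quasi-likelihood test, adjusted p = 1.00; common biological coefficient of variation 0.381). In a likelihood ratio test with that coefficient fixed at 0.2, which changes both the spread and the test, MAZ passed at an adjusted p of 2.04e-04; over the other alternatives its adjusted p was 0.773 to 1.00.

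γ-globin, the fetal β-like chain encoded by HBG1 and HBG2, took up a larger share of β-like globin counts in both knockdown libraries. It made up 38.5% of the counts of HBG1, HBG2, HBB, HBD and HBE1 in the control (exact binomial interval 38.4% to 38.6%), 72.5% in replicate 1 (72.4% to 72.5%) and 54.2% in replicate 2 (54.1% to 54.3%). The knockdown mean was 63.3% ± 12.9 (SD, n = 2), 24.8 percentage points above the control, and the smaller of the differences was 15.7 points. Adult β-globin (HBB) went from 58.0% of β-like counts in the control to 24.0% and 44.1%, and δ-globin (HBD) from 3.21% to 1.49% and 1.70%. Embryonic ε-globin (HBE1) was 0.244% of β-like counts in the control, 2.03% in replicate 1 and 0.0468% in replicate 2, so the knockdown libraries lay on either side of the control. All 5 genes lie in the β-globin cluster on chromosome 11, from the start of HBB at 5225464 to the end of HBE1 at 5269945. HBG1 made up 4.08%, 4.92% and 4.31% of γ-globin counts in the 3 libraries; the split between these near-identical copies is uncertain. The share was not tested; the interval on it covers counting error only.

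**Figure D1:**
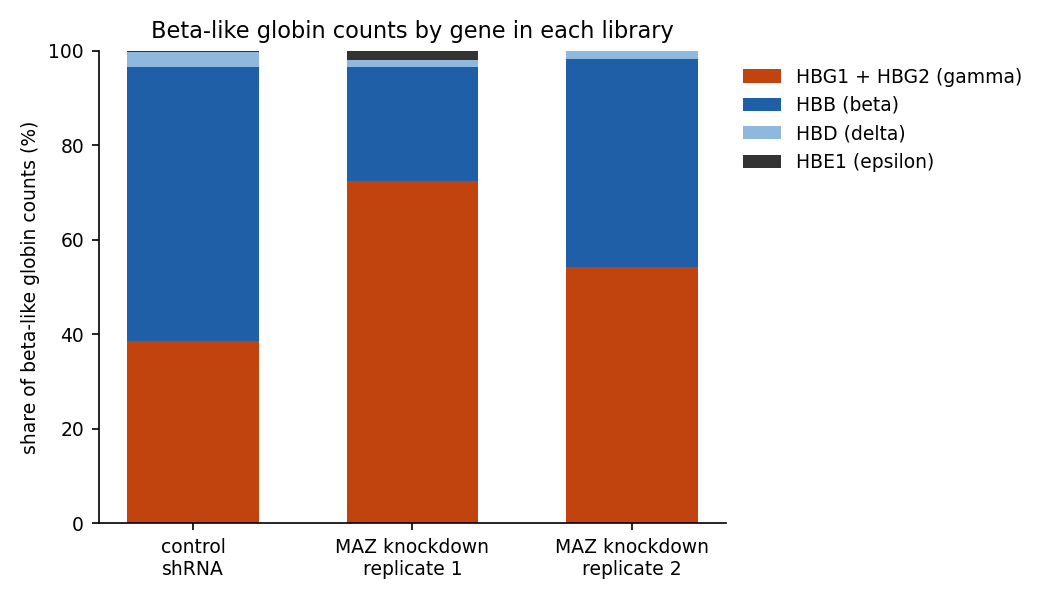
Share of β-like globin counts (%, vertical axis) taken by γ-globin (HBG1 + HBG2), HBB, HBD and HBE1 in the control and in each MAZ knockdown library, as stacked bars with 1 library per bar. The γ-globin share is 38.5% in the control, 72.5% in knockdown replicate 1 and 54.2% in knockdown replicate 2.

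As measured, the larger share went with a higher γ-globin level in replicate 1 and not in replicate 2, but the direction of γ-globin in replicate 2 turned with a correction for transcript length and GC content (an alternative chosen after seeing the data). The corrected log2 ratios were 1.31 and 0.30 for HBG2, 1.73 and 0.31 for HBG1, and -0.83 and -0.65 for HBB. Each γ-globin copy, taken singly, then had a ratio above 0 and HBB a ratio below 0 in both libraries. The replicate 2 values of HBG1 and HBG2 were smaller than the SD of corrected replicate 2 ratios over 9431 genes (0.409). Their sign rests on the trend fitted at short transcripts. Whether that trend is technical was not tested, so a higher γ-globin level in replicate 2 is not established. The summed γ-globin level was 20463 CPM in the control, 67610 CPM in replicate 1 (3.30-fold of the control) and 16818 CPM in replicate 2 (0.822-fold). HBB was 0.727-fold and 0.444-fold of the control, and HBD 0.813-fold and 0.308-fold, lower in both. The α-globin sum (HBA1 and HBA2) was 2.74-fold and 0.410-fold of the control, and embryonic ζ-globin (HBZ) 2.93-fold and 0.193-fold. As a share of all counts, γ-globin was 2.08% in the control, 5.85% in replicate 1 and 1.91% in replicate 2. Of the 12 globin genes and transcripts tested, 9 were higher in replicate 1 and lower in replicate 2, 3 were lower in both, and 0 were higher in both; with the correction these counts were 5, 3 and 4, the last being HBG1, HBG2, BGLT3 and HBQ1. None of the 12 passed the edgeR test over all genes, and 1 (HBE1, higher) passed adjusted over the list alone although its log2 ratios of 3.87 and -3.15 disagreed in sign. The globin list did not pass the list test (camera, adjusted p = 0.926), and its fitted median of 0.65 had the opposite sign to the direction of that test. Globin transcripts are short, and short transcripts as a class were higher in replicate 1 and lower in replicate 2 (below); HBB, HBG1 and HBG2 themselves have transcript lengths of 754, 779 and 614 bases.

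Known regulators of γ-globin did not move in one direction. BCL11A, a repressor of γ-globin in adult cells, was at 35.7 CPM in the control and at 17.9 and 29.5 CPM in the knockdown libraries. MYB, a progenitor transcription factor, was at 73.1 CPM and at 33.8 and 124 CPM. ZBTB7A, another γ-globin repressor, was at 159 CPM and at 225 and 129 CPM. The erythroid activators KLF1 and GATA1 were 1.32-fold and 1.35-fold of the control in replicate 1, and both 0.707-fold in replicate 2. With the length and GC correction, chosen after seeing the data, BCL11A had log2 ratios of -0.92 and -0.63, lower in both libraries. The corrected ratios of KLF1 (0.02 and -0.13) and GATA1 (0.11 and -0.15) lay nearer to the control. Those of MYB (-1.01 and 0.71) and ZBTB7A (0.48 and -0.47) still differed in sign. None of the 5 passed the edgeR test (adjusted p = 1.00 for each). Over the list of 36 tested fetal globin regulators, 6 were higher in both libraries, 5 lower in both and 25 in opposite directions (camera, adjusted p = 0.906).

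Across all genes, 3 passed the edgeR test, 1 higher and 2 lower, and 121 had an unadjusted p under 0.05. In simulated libraries at the fitted spread, the share of false calls among all calls was above the threshold of 0.05. HOXB9, a posterior homeobox transcription factor (chromosome 17, 48621156 to 48626358), fell from 89.6 CPM to 16.2 and 14.9 CPM (log2 fold change -2.53, SE 0.54, adjusted p = 0.0374). PGR, the progesterone receptor (chromosome 11, 101029624 to 101129813), fell from 68 counts in the control to 1 count in each knockdown library (adjusted p = 0.0334); the ratio to the control was 0.0183 in replicate 1 (95% counting interval 4.56e-04 to 0.105) and 0.0128 in replicate 2 (3.20e-04 to 0.0738). STRA6, a retinol transporter (chromosome 15, 74179466 to 74212259), passed as higher (log2 fold change 6.03, SE 1.22, adjusted p = 0.0299), with 3 counts in the control, 324 in replicate 1 and 10 in replicate 2. Its ratio to the control was 134 in replicate 1 (45.5 to 654) but 2.90 in replicate 2 (0.748 to 16.4), so the call rests on replicate 1, and its log2 ratio was 1.09 without that library. PGR is outside the named-gene rule, as its mean was under 5 CPM, and is named because 3 genes passed. All 3 calls were lost with DESeq2, limma-voom, robust estimation, legacy estimation or no filter on low counts, each of which called 0 genes (74, 77, 108, 100 and 217 genes at an unadjusted p under 0.05, in that order).

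**Figure D2:**
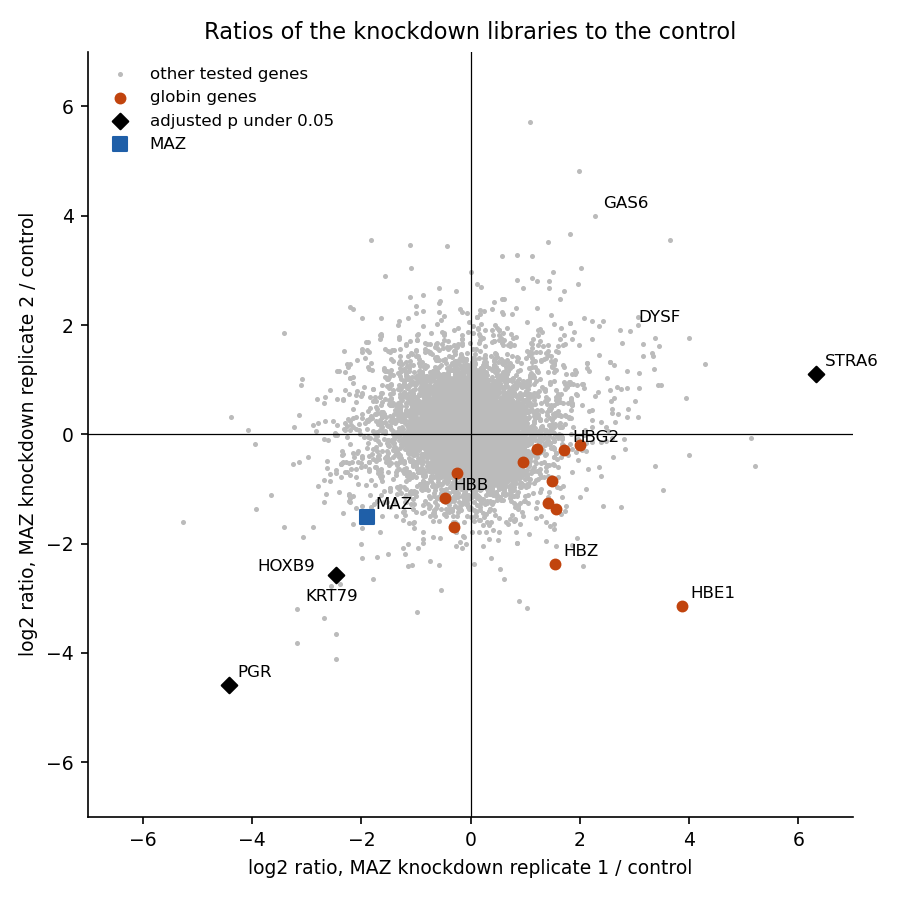
Log2 ratio to the control of each tested gene in MAZ knockdown replicate 1 (horizontal axis) and replicate 2 (vertical axis), with prior count 2; each point is a gene, and globin genes, MAZ and the 3 genes past the test are marked. MAZ lies at -1.89 and -1.52, while HBE1 lies at 3.87 and -3.15.

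The named places left were filled by genes that did not pass the test but were over 2-fold apart from the control in both knockdown libraries. Among those higher, the TAM receptor ligand GAS6 was at 0.669 CPM in the control and 3.70 and 12.5 CPM in the knockdown libraries, and the membrane repair protein DYSF at 9.97 CPM and 76.2 and 37.5 CPM. EPAS1, the oxygen-regulated transcription factor HIF-2α, was 2.51-fold and 3.07-fold of the control, and the interferon-induced gene IFIT1 2.93-fold and 2.58-fold. ACTL8, TAC3, FEZ1, ITSN1, LGR4 and MGAT5 were also in that group. Among those lower, the keratin KRT79 was at 16.1 CPM in the control and 1.66 and 1.64 CPM in the knockdown libraries (adjusted p = 0.0517). The urea cycle enzyme ASS1 was at 27.5 CPM and 4.61 and 3.92 CPM, and PHGDH, the first enzyme of serine synthesis, at 73.3 CPM and 21.2 and 11.5 CPM. PTPRC, which encodes the leukocyte antigen CD45, was 0.305-fold and 0.210-fold of the control, the potassium channel KCNN4 0.325-fold and 0.355-fold, and TRIB3, a stress-induced pseudokinase, 0.436-fold and 0.423-fold. HR, STC2, KYNU and S100A1 completed the group, with MAZ itself.

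Of the 30 gene lists tested, 8 passed camera with the preset correlation, 5 higher and 3 lower, and 3 of these had medians clearly on one side of 0 in both knockdown libraries. Glycolysis and hypoxia genes were higher (adjusted p = 1.64e-07), with 26 of 38 tested members higher in both libraries, 2 lower in both, and median log2 ratios of 0.37 and 0.53. Members chosen after their values were seen were the glycolytic enzymes ALDOC, 2.72-fold and 1.90-fold of the control, and PKM, 1.78-fold and 1.83-fold, and the hypoxia-induced EGLN3, 1.70-fold and 2.70-fold; VEGFA went the other way, at 0.672-fold and 0.903-fold. Cholesterol synthesis genes were higher (adjusted p = 3.95e-04), with 14 of 25 higher in both, 0 lower in both, and medians of 0.28 and 0.34. HMGCS1, which makes the precursor of mevalonate, was 1.57-fold and 2.04-fold of the control, and INSIG1, a sterol sensor, 1.43-fold and 1.98-fold, both chosen after their values were seen. Integrated stress and unfolded protein response genes were lower (adjusted p = 1.13e-06), with 22 of 38 lower in both, 1 higher in both, and medians of -0.38 and -0.33. The serine synthesis enzymes PHGDH (log2 ratios -1.78 and -2.65) and PSAT1 (-1.04 and -1.29; chosen after its values were seen) and the stress-induced TRIB3 (-1.20 and -1.24) were among its lower members. In these 3 lists 0 members passed the edgeR test over all genes. Adjusted over the list alone, 2 stress response members passed as lower (PHGDH and NUPR1) and 0 glycolysis members passed; that count for the cholesterol list is not used here. With an estimated correlation, 0 of the 8 calls held (adjusted p = 0.901 for each of these 3 lists), and fry, which tests whether a list's genes move one way, called 1 list, the stress response (adjusted p = 0.0104).

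**Figure D3:**
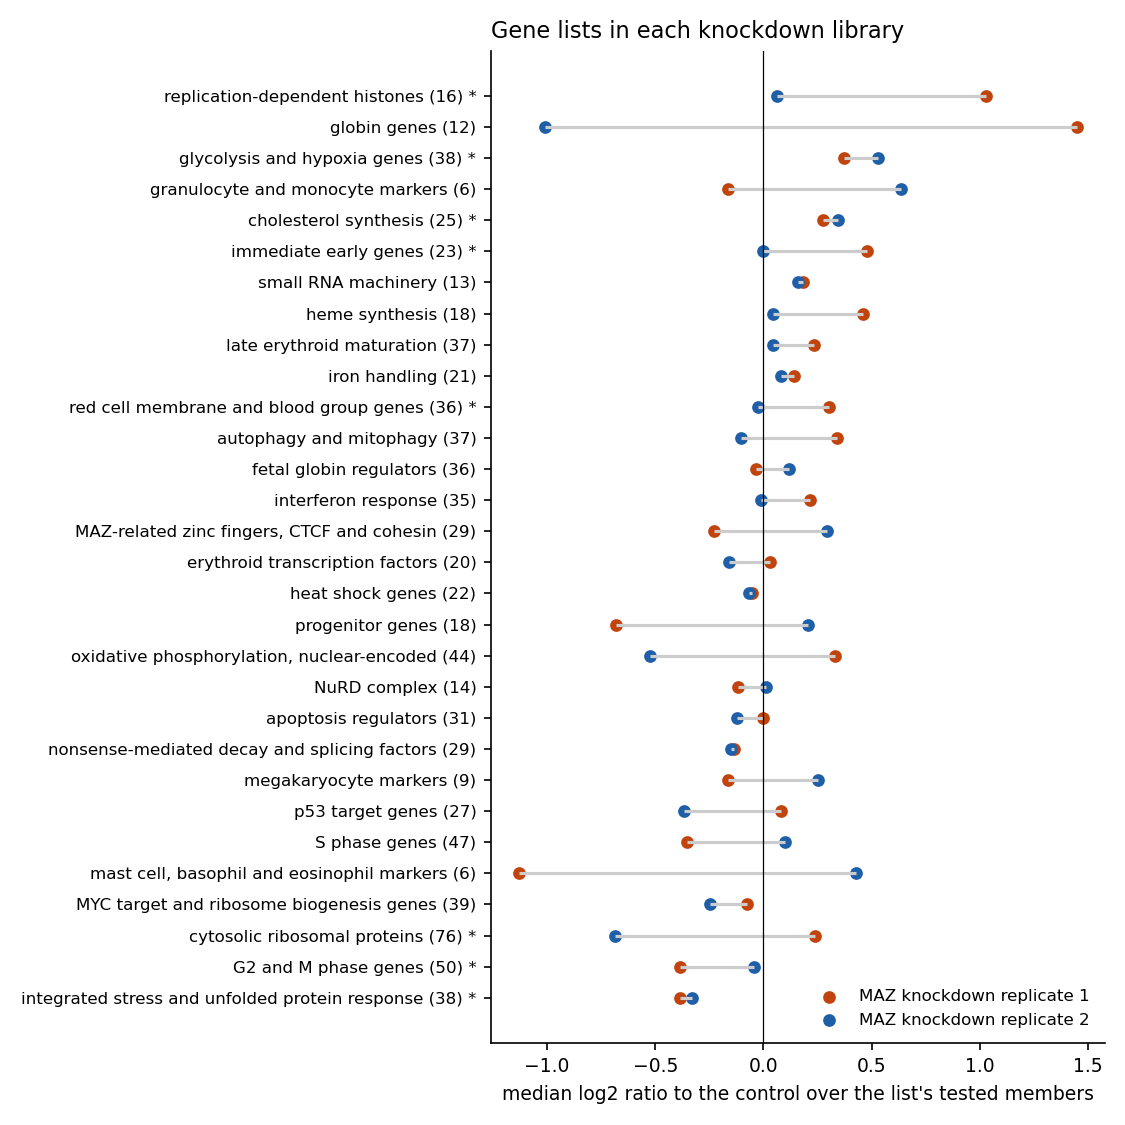
Median log2 ratio to the control (horizontal axis) over the tested members of each of 30 gene lists, in MAZ knockdown replicate 1 and replicate 2 (points, joined per list); the number of tested members is in brackets and a star marks a list past camera with the preset correlation. Glycolysis and hypoxia genes lie at 0.37 and 0.53, the stress response at -0.38 and -0.33, and globin genes at 1.45 and -1.01.

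The other 5 lists that passed differed more between the knockdown libraries. Replication-dependent histone genes were higher (adjusted p = 1.76e-03), with medians of 1.03 and 0.06 over 16 members, most of them near or below 5 CPM; H1-2, chosen after its values were seen, was at 25.7 CPM in the control and at 92.0 and 25.6 CPM. Immediate early genes were higher (adjusted p = 0.0271, medians 0.48 and 0.00 over 23 members), with 8 higher in both libraries and 4 lower in both. Among them EGR1, chosen after its values were seen, was 3.79-fold and 1.66-fold of the control, and 1 member passed adjusted over the list alone (KLF2, higher, with 1, 84 and 1 counts in the 3 libraries). Red cell membrane and blood group genes were higher (adjusted p = 0.0144, medians 0.30 and -0.02 over 36 members), with 11 higher in both and 3 lower in both. G2 and M phase genes were lower (adjusted p = 1.76e-03, medians -0.39 and -0.04 over 50 members), with 23 lower in both and 0 higher in both. Cytosolic ribosomal protein genes were lower (adjusted p = 1.76e-03), but 66 of 76 were higher in replicate 1 and lower in replicate 2, with medians of 0.24 and -0.69. Again 0 members of these lists passed over all genes. With an estimated correlation the adjusted p was 0.930 for ribosomal protein genes and 0.901 for each of the other 4.

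The 22 lists that did not pass (adjusted p from 0.0717 to 0.978) included several whose medians lay on opposite sides of the control. Progenitor genes had medians of -0.68 and 0.21, and of 18 members 11 were lower in replicate 1 and higher in replicate 2; KIT, the stem cell factor receptor, was 0.361-fold and 2.85-fold of the control, and GATA2 0.643-fold and 2.66-fold, both chosen after their values were seen. Mast cell, basophil and eosinophil markers had medians of -1.13 and 0.43 over 6 members, S phase genes -0.35 and 0.10 over 47, and nuclear-encoded oxidative phosphorylation genes 0.33 and -0.52 over 44. MAZ-related zinc fingers, CTCF and cohesin genes had medians of -0.23 and 0.29 over 29. Megakaryocyte markers (9 tested) had medians of -0.17 and 0.25, and granulocyte and monocyte markers (6 tested) -0.17 and 0.64. Interferon response genes, IFIT1 among them, had medians of 0.21 and -0.01 over 35 (camera, adjusted p = 0.334). Of these, 10 were higher in both libraries and 11 lower in both. Heme synthesis genes (0.46 and 0.04 over 18), iron handling genes (0.14 and 0.08 over 21) and late erythroid maturation genes (0.24 and 0.04 over 37) had medians above 0 in both libraries. Lymphocyte markers were not tested, with 2 members past the filter.

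Over all genes, the knockdown libraries resembled each other less than either resembled the control. The SD of the log2 difference was 0.894 between the knockdown libraries, 0.659 between the control and replicate 1 and 0.598 between the control and replicate 2. Across the 12712 genes, which are not independent replicates, the 2 ratios to the shared control had a Pearson correlation of -0.01 and a Spearman correlation of -0.15. Unchanged libraries with a shared control gave a simulated Pearson correlation of 0.498, and a covariance of 0.351 against the -0.0036 observed. The sign was the same for 42.3% of genes. At least 2-fold apart in the same direction in both libraries were 125 genes higher and 84 lower. Independent lists of the observed sizes would share 27.8 and 22, and the simulated unchanged libraries gave 561 and 392 at the wide fitted spread. Part of the excess over independent lists may come from the shared control. Of the 125 and 84 genes, 28 and 20 were among the 9475 genes with a mean of 5 CPM or more. Simulated unchanged libraries gave 286 and 183 there. Most of the 125 and 84 therefore had a mean under 5 CPM, where counting noise in the shared control is larger. In opposite directions, 36 genes were at least 2-fold higher in replicate 1 and lower in replicate 2, and 101 the reverse. Simulated unchanged libraries gave 24.1 (10 to 36) and 26.8 (15 to 38), and independent lists 16.4 and 37.2. The simulated libraries held more genes 2-fold apart in a single library than the data. They had 1334 higher in replicate 1 against 547 observed, and 1323 lower in replicate 2 against 382. Their range therefore does not decide whether the 36 is unusual, while the 101 lay above it and above the value of independent lists.

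Part of this spread followed transcript length. Across 9431 genes with a mean of 5 CPM or more, the Spearman correlation of the ratio with transcript length was -0.28 in replicate 1 and 0.54 in replicate 2, and with GC content 0.28 and -0.25. In the 10% of genes with the shortest transcripts (median 998 bases) the median log2 ratio was 0.33 in replicate 1 and -0.47 in replicate 2, against -0.11 and 0.38 in the 10% with the longest (median 8901 bases). With this trend taken out of each ratio, an alternative chosen after seeing the data, the Pearson correlation of the 2 ratios over these genes went from -0.17 to -0.03. Their covariance went from -0.041 to -0.0056. The SD of the log2 difference between the knockdown libraries went from 0.749 to 0.633, and the genes 2-fold apart between them from 1478 to 908. After this correction the median of ribosomal protein genes was -0.02 and -0.26, that of oxidative phosphorylation genes 0.12 and -0.19, and that of globin genes 0.83 and -0.54. All 3 calls of single genes were lost in that fit, which called 0 genes with edgeR (121 at an unadjusted p under 0.05), although their log2 fold changes were about as large: 5.92 (SE 1.61) in place of 6.03 (SE 1.22) for STRA6 and -6.09 (SE 1.22) in place of -5.88 (SE 1.23) for PGR. For HOXB9 it was -2.51 (SE 0.40) in place of -2.53 (SE 0.54) and the unadjusted p 7.11e-06 in place of 8.83e-06. Its adjusted p of 0.0881 (7.39e-10 to 0.397 over the alternatives) came from its rank, since no gene had a smaller p after correction.

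**Figure D4:**
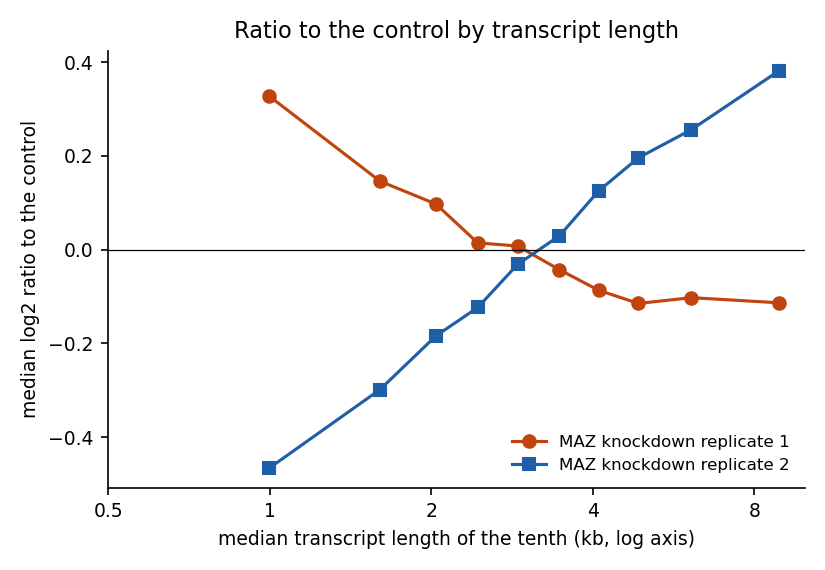
Median log2 ratio to the control (vertical axis) against the median transcript length (kb, log axis) in 10 groups of equal size of 9431 genes ordered by length, for each MAZ knockdown library. Replicate 1 goes from 0.33 in the shortest group to -0.11 in the longest, and replicate 2 from -0.47 to 0.38.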

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

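The length and GC correction was chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the control is a single library. The count of 3 differentially expressed genes was 5 with RLE and 5 with upper-quartile scaling, 142 (101 higher, 41 lower) with the coefficient of variation fixed at 0.2, and 0 with no filter on low counts, DESeq2, limma-voom, robust estimation, legacy estimation and the length and GC correction (217, 74, 77, 108, 100 and 121 genes at an unadjusted p under 0.05). Removing globin genes and the stricter filter of a mean of 5 CPM gave 3 genes each, of which 3 and 2 were among the 3 reported. The fitted spread comes from 1 pair of libraries that were farther apart than either was from the control, and a fixed spread is an assumption, used with another test; the cause was not tested. MAZ was lower under every setting, and passed only with the fixed coefficient (log2 fold change -1.69); its ratio was -1.89 to -1.52 with either knockdown library left out.

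The γ-globin share of β-like counts was above the control by 24.8 points, by 25.2 points with HBB as the only other chain, and by 15.7 to 33.9 points with either knockdown library left out. As a share of all counts the difference was 1.81 points, on a smaller scale by construction, and was negative in replicate 2. The 209 genes 2-fold apart in both libraries were 47 with the stricter filter, which kept 9492 of the 12712 genes. Most of the 209 therefore had a mean under 5 CPM. The count was 1029 to 1278 with either library left out, where 1 library decides. With RLE, a prior count of 0.5 and the correction it was 206, 242 and 194. The correlation of the ratios was -0.18 with the stricter filter, 0.022 with a prior count of 0.5 and 0.081 with the correction; the cause was not tested.

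Of 30 lists, 8 passed, against 0 with an estimated correlation, 1 with fry, 13 of 27 with the stricter filter, 8 with RLE and 10 with the correction. All 8 passed under RLE and under the correction. An estimated correlation has 1 residual degree of freedom and did not call a simulated list that was moved, so its lack of calls says nothing about stability. Histones had too few members for the stricter filter. List medians turned sign with 1 library left out for red cell membrane genes (-0.025 to 0.30), immediate early genes (-7.72e-04 to 0.48) and ribosomal protein genes (-0.69 to 0.24).

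Of 520 alternative values for 41 named genes other than MAZ, 462 kept their direction and side of the threshold or, with a library left out, stayed within 1 SD, 12 moved further, 18 lost and 22 gained a call, and 6 changed sign, all of genes not past the test (sign changes of such genes with a library left out are not counted here). With limma-voom these were HBZ (-0.32), MYB (-0.18), KLF1 (-0.029) and GATA1 (-0.014), and with the correction KLF1 (-0.051) and GATA1 (-0.013). The SD used with a library left out was that of the gene's own 2 knockdown ratios, so it widens where the libraries disagree. HBG2, at 1.03 in the main fit, counted among the 462 at -0.29 without replicate 1. The 462 are therefore no measure of stability. The adjusted p ran from 7.39e-10 (fixed coefficient) to 0.397 (limma-voom) for HOXB9 and from 4.61e-14 (fixed coefficient) to 0.709 (DESeq2) for PGR. Depth was not the limit for globin genes or MAZ; it limits STRA6, PGR and KLF2, which have 1 to 3 counts in a library.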

Other observations

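The tests of explanations in this part were chosen after the results were seen. The HOXB genes lie side by side on chromosome 17, and several of them besides HOXB9 were lower in both knockdown libraries, none past the test. HOXB8 had 166 counts in the control, 23 in replicate 1 and 13 in replicate 2, which is 0.182-fold and 0.0795-fold of the control on the scale with prior count 2 (log2 fold change -3.08, SE 0.80, edgeR adjusted p = 0.232). At low counts, HOXB5 had 32, 4 and 25 counts (log2 ratios -2.28 and -0.52) and HOXB6 had 14, 1 and 9 counts, so both were mainly lower in replicate 1. At the other end of the cluster, HOXB2 was at 28.3, 28.7 and 27.9 CPM in the 3 libraries, HOXB3 had log2 ratios of -0.10 and 0.49, and HOXB4 was at 34.2, 24.7 and 33.2 CPM. HOXB7, next to HOXB8, was at 14.7, 14.1 and 8.63 CPM. These genes were chosen after their values were seen.

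The knockdown libraries deviated from the control in opposite directions in many gene groups. A mix-up that left a knockdown library without knockdown is argued against by MAZ, whose log2 ratio was -1.52 in the library nearer to the control, a value reached by 0.0832% of 1202 genes of like expression. Over 9431 genes, taking out the length and GC trend moved the correlation of the 2 ratios from -0.17 to -0.03. The fitted trend did not account for all of the gap in globin and progenitor genes. With it taken out, the median gap between the knockdown libraries was still 1.00 for globin genes and -0.75 for progenitor genes. Each lay beyond every one of 10000 random lists. Those lists were matched on expression only and drawn without regard to shared regulation, so they give no chance level for genes that move together. Both lists were chosen after their opposite medians were seen. A difference in erythroid maturation between these cultures is a candidate for part of the pattern. In 5 of 7 lists the corrected gap lay outside the central 95% of random lists on the side it predicts. Globin and red cell membrane genes were higher, and progenitor, S phase and G2 and M phase genes lower, in replicate 1 than in replicate 2. Heme synthesis and late maturation lists lay on that side at percentiles 95.1 and 93.1. The prediction was written after the medians of these lists were seen, so the count largely restates them. Lists with no such prediction also lay outside, among them autophagy (percentile 99.99), p53 targets (99.7) and cholesterol synthesis (1.36). Replication-dependent histones lay at 99.7, on the side opposite to S phase genes. Whether a maturation difference came from the hairpins, the degree of knockdown or the cultures is open. Setting replicate 1 alone against the other libraries gave 54 genes past the edgeR test and setting replicate 2 alone gave 0, against 3 for the control alone (1760, 1586 and 121 at an unadjusted p under 0.05); 3 splits are too few for a share under 0.05, and each spread comes from a single pair of libraries, of which the knockdown pair was the farthest apart, so these counts add no separate evidence.

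The integrated stress and unfolded protein response list had medians below 0 in both knockdown libraries, with 22 of 38 members lower in both and 0 past the test over all genes (camera, adjusted p = 1.13e-06, and 0.901 with an estimated correlation). The fitted length and GC trend did not account for all of this shift. After correction the list medians were -0.34 and -0.15, at percentiles 0 and 1.23 of random lists matched on expression only, drawn without regard to shared regulation. A higher stress response in the single control library is a candidate explanation that cannot be told apart from an effect of the knockdown: the median over its genes of the corrected gap between the knockdown libraries was -0.0448, which is not the difference of the list medians and does not decide it, and there is no other control library to compare.

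Genes on chromosome 20 were higher in knockdown replicate 2. Over 262 genes with a mean of 5 CPM or more, the median log2 ratio there was 0.18, and 0.22 after the length and GC correction, above all of 10000 matched random gene sets, so that trend is not the whole cause; the other 22 chromosomes analysed lay between -0.05 and 0.07, and chromosome 20 in replicate 1 at -0.02. A few strongly changed genes are argued against, since 76.0% of the 258 genes under 2-fold apart lay above 0, against 43.5% to 55.6% in the central 95% of random sets. Extra copies of chromosome 20 in part of these cells remain a hypothesis for the shift. In 100% of the 10 windows of 5000000 bases with 10 or more genes the median lay above 0. Of the 3 windows with fewer genes 1 (10000001 to 15000000, 7 genes) lay at -0.24. Because most genes of the chromosome lay above 0, such window medians would follow from any cause that acts along it. The windows therefore do not tell extra copies from other causes. DNA copy number was not analysed here, and a regulatory cause that acts on many genes of the chromosome stays open.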
